A study of Mus musculus with 4 samples.

How the data were processed

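Total RNA from 4 cultures of J1 mouse embryonic stem cells was measured on 4 Affymetrix 3′ expression arrays, 1 per condition: scramble, scramble with PRDM14, Tet1/Tet2 knockdown, and Tet1/Tet2 knockdown with PRDM14. The groups were taken from the sample titles. Per the labels' protocols, the RNA was labelled with a GeneChip 3′ IVT Express kit. The deposited values are log2 probe set signals that the authors had already brought to a common distribution, with quartiles within 0.02 of each other on the 4 arrays. The log base was inferred from the range, from 2.78 to 13.2, since a natural log of that size would exceed a scanner's range. Affymetrix Expression Console is named in the submitters' processing notes. Its version, the summary method and the background correction are not given in the sources used here, so a compression of low signals by that step cannot be assessed. No genome build is named, and no coordinates are printed.

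The table held 45141 probe sets, of which 104 were array controls. A platform annotation named 1 gene for 28898 probe sets, several for 551 and none for 15588, and only the first kind entered the gene results. The Entrez identifiers of 28689 probe sets were found in the RefSeq gene table of the mouse reference, and 0 symbols changed. These gave 17097 genes. A gene was represented by its probe set with the highest mean over the 4 arrays. The expression filter was the median of all values of named probe sets, 5.40. It is not a measure of background, which was not determined per probe set, and the nonspecific control probe sets read from 2.78 to 8.20 with rising GC content. No per-sample column was left out.

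A gene was called higher or lower when the 2 arrays compared differed by at least 2-fold and the higher of them reached the filter. With 1 array per condition such a call is a size rule and not a test. The spread between probe sets of 1 gene was given as a technical yardstick, which covers neither cultures nor arrays. The dependence on the knockdown was the difference of the 2 PRDM14 differences. Comparisons that share an array were not correlated. The average effects were fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with an intensity trend, in an additive model with 1 residual degree of freedom per gene, and adjusted by Benjamini-Hochberg at 5% over all genes tested and, separately, over each fixed list alone.

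In all 23 gene lists were fixed before the data were examined: target genes, DNA methylation, base excision repair and demethylation, naive pluripotency, general pluripotency, primed epiblast, FGF and ERK signalling, methylated germline promoters, Rhox cluster, primordial germ cell, 2-cell-like, trophectoderm, primitive endoderm, mesoderm and definitive endoderm, neuroectoderm, fibroblast and feeder, imprinted, Polycomb, p53 targets, interferon response, cell cycle, stress and hypoxia, and housekeeping. Some genes stand on more than 1 list, for example Ifitm3 among primordial germ cell and interferon genes and Zic2 among primed epiblast and neuroectoderm genes. For lists with at least 3 members above the filter, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A percentile describes these arrays and is not a p-value. Over the 23 lists and 5 contrasts 104 percentiles were computed, of which 41 lay below 2.5 or above 97.5, where 5.2 would be expected for random lists. Random lists were drawn gene by gene, so they lack the shared regulation of real lists. The 5 contrasts also share arrays. A single array that stands apart could thus move several percentiles, and the excess is not evidence of effects of the conditions.

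Named genes followed a rule set before the data were examined: the target and DNA methyltransferase genes, the 12 largest called differences in each direction of each contrast, up to 4 members of each list with the largest difference in each comparison, and genes passing the additive fit. Where probe sets of a named gene disagreed in direction by an amount that bears on the call, or a leading gene had a probe set under 2-fold, the text gives both. Genes called in both backgrounds, and list members that the text names because of a call or a contrast with another comparison, were named after their values were seen.

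The procedure was tested on simulated data for the PRDM14 comparison, with 10519 genes, noise of SD 0.121 and 200 changed genes. The 2-fold rule called 46% and 42% of the genes changed 2-fold in the 2 backgrounds and 100% of those changed 3-, 4- or 8-fold. Limma recovered 100% at each size with 19 false calls among 10319 unchanged genes. The simulated noise had the same SD for every gene, which lets limma pool its variance over genes. In the data the variance differed between genes, with a median of 2.25 prior degrees of freedom in the fit. That recovery therefore does not carry over to the measured arrays. Alternatives were a 1.5- or 3-fold threshold, no filter or one at the 75th percentile, median centring, quantile or cyclic loess normalization, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, and eBayes without a trend. An alternative chosen after the data were seen raised every value below the filter to the filter, which gives the difference counted from the filter upward, and values from it are called raised values.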

Results

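Gene expression was measured in mouse J1 embryonic stem cells, a pluripotent line kept here without feeder cells in serum and LIF, under 4 conditions that crossed 2 factors. Per the labels, the first factor was overexpression of PRDM14, a PR-domain protein of pluripotent and germ cells, in a line induced with doxycycline. The other factor was the combined knockdown of Tet1 and Tet2, which encode dioxygenases that oxidise 5-methylcytosine, set against a scramble control. The question given for the series was what TET1 and TET2 do in gene regulation by PRDM14. Each condition was represented by 1 Affymetrix array, 4 in all, so there were no replicates and no difference between conditions could be set against a spread within a condition. The number of arrays limits the precision of every value. The median log2 signal lay between 5.09 and 5.11 on the 4 arrays, and 10519 named genes reached the expression filter on at least 1 array.

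Of the genes targeted in the design, Tet2 was lower on both knockdown arrays. Its brightest probe set read 8.46 on the scramble array and 7.50 on the knockdown array, a log2 difference of −0.96, and 9.33 and 8.15 on the corresponding arrays labelled with PRDM14, a difference of −1.18. The other Tet2 probe set above the filter gave −0.56 and −0.58. Tet2 was also higher on the arrays labelled with PRDM14, by 0.87 in scramble and 0.65 in knockdown cells, while the other probe set gave 0.22 and 0.20. Tet3, the third member of the family, differed by at most 0.14 in any of the 4 comparisons. Tet1 was not analysed here, so the Tet1 part of the knockdown label was not checked. Prdm14 itself read 4.53, 4.83, 4.35 and 4.61 on the scramble, scramble with PRDM14, knockdown and knockdown with PRDM14 arrays, below the filter value of 5.40 on all 4. Its differences of 0.30 and 0.26 were under 2-fold on a probe set that did not pass the filter and gave no check of the PRDM14 labels, and whether the probe set covers the introduced transcript is not known. The conditions are accordingly called arrays labelled with PRDM14, and every direction of a PRDM14 difference rests on those labels.

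The first comparison set the scramble array labelled with PRDM14 against the scramble array. Of 10366 genes above the filter, 113 were at least 2-fold higher and 104 at least 2-fold lower on the array labelled with PRDM14. The higher genes were led by Id1, an inhibitor of basic helix-loop-helix factors, at 12.4-fold (6.57 against 10.20), and its relative Id2 was 5.80-fold higher. Vim (vimentin), Cdh2 (N-cadherin) and Nefl (neurofilament light chain) had log2 differences of 2.73, 2.73 and 2.59, and Coch, P3h4, Ifitm3, Epop, Trh, Spink1 and Upp1 lay between 2.14 and 2.94. Cdh2 read 4.43 on the scramble array, below the filter, and differed by 1.76 with values below the filter raised to it, and second probe sets gave 0.83 for Cdh2 and 0.71 for Nefl. The lower genes were led by Sycp3, a component of the synaptonemal complex of meiotic chromosomes, at −2.92 (8.42 against 5.50). Gm20767, Nupr1, Dppa3, Cebpb, Dusp4, AF067061, Coq2, Prkar2b, Tfap2c, Stag3 and Gkap1 followed, between −2.66 and −1.71, although a second probe set of Cebpb gave −0.03. Between probe sets of 1 gene the same difference had a pooled SD of 0.22, and in 69 of 78 called genes with several probe sets above the filter all probe sets pointed the same way, and in 26 all were past 2-fold. In 51 of the 217 calls 1 array read below the filter, and 101 higher and 84 lower genes were counted with raised values.

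The list of methylated germline genes had a median of −0.53 in scramble cells, below all 10000 random lists of the same size and expression. Of 25 measured genes whose promoters are methylated in somatic cells and whose products act in germ cells, 5 were at least 2-fold lower and none was 2-fold higher on the array labelled with PRDM14, and 18 had a difference below 0. The 5 were Sycp3, the meiotic cohesin subunit Stag3 (−1.73), the germ cell helicase Ddx4 (−1.41), the transcription factor Dmrt1 (−1.38) and the RNA-binding protein Dazl (−1.26). Stag3 was just under 2-fold with raised values, and the list median was then −0.48. Among 12 primordial germ cell genes, Dppa3 (−2.51), Tfap2c (−1.79), Kit (−1.08) and Prdm1 (−1.02) were lower and Ifitm3 (2.45) was higher, and the median of −0.01 lay at the 42.6th percentile. In the X-linked Rhox homeobox cluster, Rhox6 (−1.22) and Rhox9 (−1.16) passed the 2-fold rule while Rhox5 differed by 0.32, and the median of the 4 measured genes was −0.78, below all random lists. Rhox6 and Rhox9 read 4.37 and 4.59 on the array labelled with PRDM14, below the filter. With raised values they were at −0.19 and −0.36, under 2-fold, and the list median was −0.27, at the 1.83rd percentile.

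The DNA methylation and primed epiblast lists had medians above 0 on the same array, with members on both sides. Of 9 DNA methylation genes 6 were above and 3 below 0 and 1 was called, and the median of 0.49 lay at the 99.96th percentile. The de novo methyltransferase Dnmt3b differed by 1.32, and by 1.36 on its second probe set, its cofactor Dnmt3l by 0.95 and the maintenance factor Uhrf1 by 0.90, while Dnmt1 differed by −0.17 and Dnmt3a by −0.35. Of 11 primed epiblast genes 7 were above and 4 below 0, 2 were called higher, Cdh2 and the POU factor Pou3f1 (1.15), and their median of 0.40 lay above all random lists. Without the expression filter that median was 0.003, and Pou3f1 was at −0.04 on a second probe set and at 0.84 with raised values. Neuroectoderm genes had a median of 0.73 over 6 members, above all random lists, but 0.023 over all members without the filter, and Nefl was the member called. FGF and ERK targets went both ways, with Spry4 at 1.64 (0.76 with the mean of its probe sets), Myc at 1.32 and Dusp4, a phosphatase of ERK kinases, at −2.15, and a median of 0.01 at the 53.7th percentile.

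Stress and hypoxia genes were split in scramble cells, with the glucose transporter Slc2a1 (1.44), Nqo1 (1.31) and Hspb1 (1.21, and 0.08 on another probe set) higher and Asns (−1.37), Ddit3 (−1.26) and Chac1 (−1.15) lower, and their median of 0.30, above all random lists, was 0.038 without the filter. The primitive endoderm list, in which none of 13 members was called, had a median of 0.17 (99.6th percentile), the imprinted list 0.15 (99th percentile) and the interferon list 0.20 (99th percentile). The cell cycle list had a median of −0.14 (0.36th percentile) but a mean of 0.04, with Ccnd2 at 1.31 and Ccne2 at 1.11. The naive pluripotency (83rd percentile), general pluripotency (85.5th), base excision repair (79.1st), trophectoderm (95.2nd), mesoderm and definitive endoderm (88.4th), fibroblast and feeder (72.8th), Polycomb (41st), p53 target (11.5th) and housekeeping (39.9th) lists lay within the central 95% of random lists. The 2-cell-like list had 2 measured members and was given no percentile.

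The scramble array, the baseline of this comparison and of the knockdown comparison without PRDM14, stood further from the rest than the other arrays. On it 49 genes lay at least 2-fold above or below all 3 other arrays, against 27 on the scramble array labelled with PRDM14, 7 on the knockdown array and 12 on the knockdown array labelled with PRDM14. The root mean square distance from the mean of the other 3 arrays was 0.281, 0.258, 0.199 and 0.205 in that order. By that measure the scramble array labelled with PRDM14 lay nearly as far out. The 18S rRNA control probe set at the 5′ end read 11.79 on the scramble array and 10.95 to 11.37 elsewhere. Against the mean of the other 3 arrays, the BioB, BioC, BioDn and CreX spike-in probe sets differed by 0.091 to 0.294. Second probe sets for these spike-ins differed by 0.001 to 0.206. The DapX spike-in differed by −0.258 to −0.132, and second probe sets for it by −0.143 to −0.0065. All DapX probe sets read highest on the scramble array labelled with PRDM14. The middle probe set read 6.91 on the scramble array, 7.40 on that array, and 7.03 and 7.06 on the knockdown arrays. The Actb controls differed by −0.335 to −0.254 and the Gapdh controls by −0.234 to −0.158. The cause of these control differences was not tested. Neither of the 2 comparisons that start from the scramble array can be made without it, so no count free of it could be given. With raised values the 4 counts were 40, 25, 6 and 9. The dependence on the knockdown, given last, also contains that array.

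**Figure D1:**
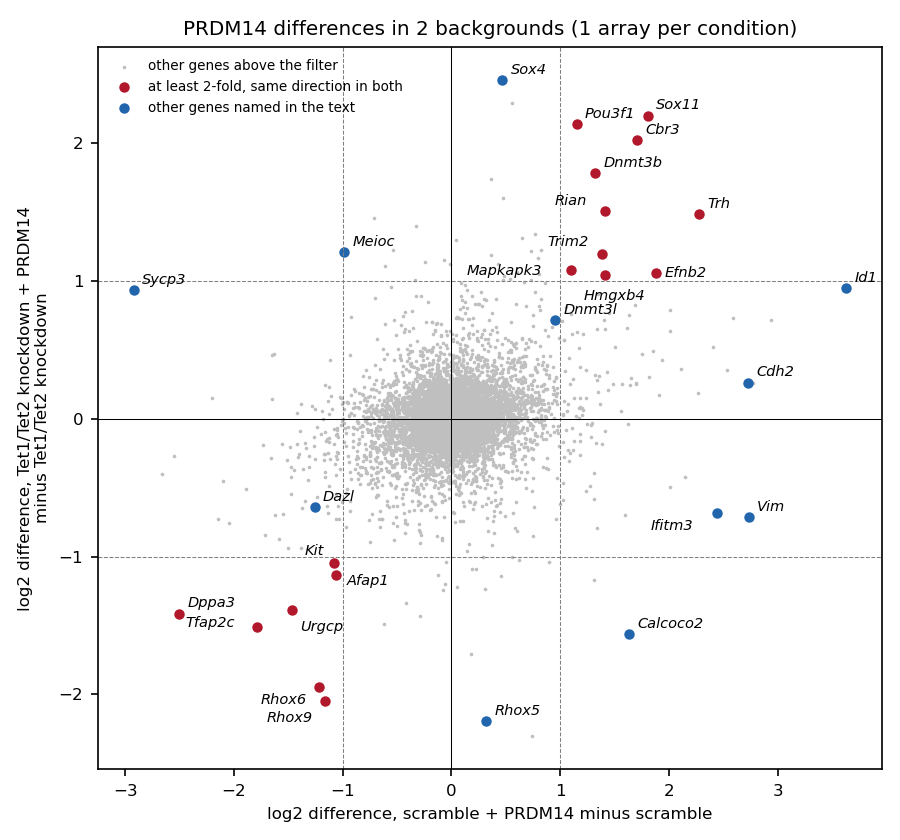
Log2 difference between the array labelled with PRDM14 and its control in scramble cells (horizontal axis) and in Tet1/Tet2 knockdown cells (vertical axis), 1 point per gene above the expression filter on any array, with dashed lines at 2-fold. Dnmt3b (1.32 and 1.78) and Dppa3 (−2.51 and −1.41) lie past 2-fold in the same direction on both axes, whereas Sycp3 (−2.92 and 0.93) and Vim (2.73 and −0.72) lie on opposite sides of 0.

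The second comparison set the knockdown array labelled with PRDM14 against the knockdown array. Of 10311 genes, 37 were at least 2-fold higher and 28 at least 2-fold lower. Sox4 led the higher genes at 5.49-fold, and the SOX factor Sox11 (2.20), the zinc transporter Slc39a8 (2.29), Pou3f1 (2.14), Cbr3 (2.02), Dnmt3b (1.78), Ripk4 (1.74), the tight junction genes Cldn4 (1.60) and Cldn7 (1.40), the imprinted noncoding RNA Rian (1.51), Trh (1.48) and Kcnk1 (1.45) followed. With the mean of a gene's probe sets in place of the brightest, Sox11 was at 0.89 and Rian at 0.99, and the lowest probe sets of Sox4, Sox11, Rian, Pou3f1 and Ripk4 gave 0.38, 0.18, 0.08, 0.51 and 0.59. The lower genes were led by the secreted protease Htra1 (−2.30) and 3 Rhox genes, Rhox5 (−2.19), Rhox9 (−2.05) and Rhox6 (−1.95), followed by Aard, Calcoco2, Tfap2c, Mgarp, Slit2, Dppa3, Urgcp and Aqp3 between −1.70 and −1.33. With raised values Slc39a8 was at 0.77 and Slit2 at −0.72, under 2-fold, and 31 higher and 25 lower genes were counted. A probe set of Aqp3 gave −0.59. The pooled SD between probe sets of 1 gene was 0.15, and in 18 of 19 called genes with several probe sets all pointed the same way and in 4 all were past 2-fold.

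In knockdown cells the primed epiblast list lay above and the Rhox list below all random lists. Of 12 primed epiblast genes 11 had a difference above 0 and 2 were called, Pou3f1 and the homeobox gene Otx2 (1.31), with a median of 0.47. Of 4 Rhox genes 3 were called lower and Rhox13 was at −0.67, with a median of −1.997. Rhox9 and Rhox6 read 4.87 and 4.77 on the array labelled with PRDM14, below the filter, and with raised values they were at −1.52 and −1.32 and the median at −1.42, still below all random lists. Dnmt3b was at 1.78 on its brightest probe set and 1.84 on the other, Dnmt3l at 0.72, Uhrf1 at 0.45, Dnmt3a at 0.16 and Dnmt1 at 0.05. The DNA methylation list had a median of 0.16 (99.5th percentile), or 0.095 with the mean of a gene's probe sets, which is within the random range. Naive pluripotency genes had a median of −0.13 (0.11th percentile), and 12 of 16 were below 0, with Tcl1 at −1.04, Klf4 at −0.61, Esrrb at −0.49 and Tfcp2l1 at −0.47. Of 12 primordial germ cell genes 3 were called lower, Tfap2c (−1.51), Dppa3 (−1.41) and Kit (−1.05), and the median of −0.11 (0.83rd percentile) was −0.070 with the mean of probe sets and then within the random range.

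The methylated germline genes did not share a direction in knockdown cells. Of 19 measured members 8 were above and 11 below 0, Meioc was the member called, at 1.21 (0.89 with raised values), and the median of −0.03 lay at the 24.2nd percentile. Sycp3 was at 0.93 and Dazl at −0.64. The FGF and ERK list had a median of 0.16 (99.98th percentile) with no member called, and the neuroectoderm list 0.26 (99.9th percentile), which was 0.014 without the filter. The general pluripotency list, at 0.08, lay just outside the central 95% of random lists, but within it without the filter (0.083) or with the mean of probe sets (0.079), and the stress and hypoxia list, at −0.07, at the 2.35th. Base excision repair (35th percentile), trophectoderm (73.7th), primitive endoderm (80.5th), mesoderm and definitive endoderm (14.8th), fibroblast and feeder (56.4th), imprinted (94.9th), Polycomb (39.2nd), p53 target (37.5th), interferon (32.2nd), cell cycle (12.2nd) and housekeeping (56.1st) lists lay within the central 95% of random lists.

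**Figure D2:**
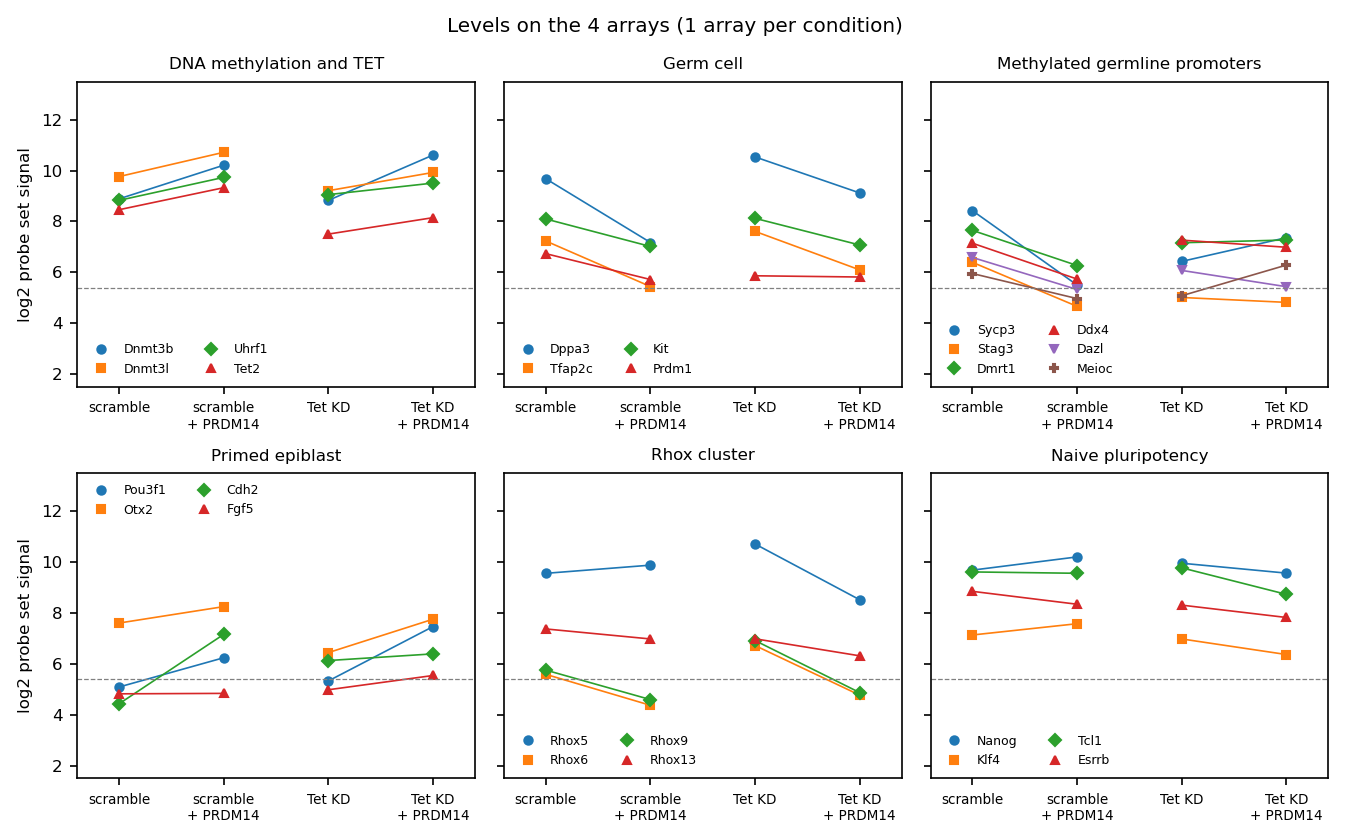
Log2 signal of named genes (brightest probe set) on each of the 4 arrays, 1 point per gene and array, with lines joining the arrays of 1 background and a dashed line at the expression filter of 5.40. Dnmt3b was higher and Tfap2c lower on the arrays labelled with PRDM14 in both backgrounds, while Sycp3 went from 8.42 to 5.50 in scramble cells and from 6.43 to 7.36 in knockdown cells.

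The third comparison asked how the knockdown differed from scramble without PRDM14. Of 10351 genes, 64 were at least 2-fold higher and 46 at least 2-fold lower on the knockdown array. Vim (2.37), Id1 (2.28), the scavenger receptor Colec12 (2.18), Htra1 (2.17), Vgll3 (2.08) and Nefl (2.08) led the higher genes, with Mex3b, Id2, Rnf128, Cdh2, Mettl9 and Sgms2 between 1.55 and 1.86. The immediate early gene Egr1 (−2.16) led the lower genes, followed by Gm20767 (−2.11), the stress-induced Nupr1 (−2.09), the thioredoxin-binding protein Txnip (−2.01), Sycp3 (−1.99) and Sox4 (−1.82), and by AF067061, Phkb, Gpt2, Cebpb, Arrdc4 and Psat1 between −1.82 and −1.45. A second probe set gave 0.06 for Cebpb and −0.27 for Gpt2, and Sox4 was at −0.75 with the mean of its probe sets. Other probe sets gave 0.68 for Nefl, 0.47 for Cdh2, −0.20 for Sox4 and −0.94 for Txnip. With raised values Colec12 (0.65), Vgll3 (0.81), Mex3b (0.12), Cdh2 (0.73), Sgms2 (0.96) and Phkb (−0.96) were under 2-fold, and 52 higher and 39 lower genes were counted. The pooled SD between probe sets was 0.21, and in 12 of 35 called genes with several probe sets all were past 2-fold. Vim, Id1, Nefl, Sycp3 and Nupr1 also led the first comparison in the same direction, but both comparisons subtract the same scramble array, so that likeness was not read as a shared effect.

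Among the lists, 3 of 4 Rhox genes were called higher in the knockdown without PRDM14, Rhox9 (1.16), Rhox5 (1.15) and Rhox6 (1.13), and the median of 1.14 lay above all random lists. These genes read highest on the knockdown array, at 6.91, 10.71 and 6.72. The lower Rhox values with PRDM14 in knockdown cells are counted from the same array, so the 2 Rhox results are not separate findings. The p53 target list had a median of −0.29, below all random lists, with Ccng1 at −0.86 on its brightest probe set and 0.03 on another, while Perp was higher at 1.27. The methylated germline list had a median of −0.15 (0.06th percentile) with Sycp3, Stag3 (−1.38) and Syce1 (−1.10) called lower, of which Stag3 and Syce1 were under 2-fold with raised values. The naive pluripotency list was at −0.16 (0.4th percentile) with no member called, and the stress and hypoxia list at −0.09 (1.33rd percentile), with Ddit4 (−1.25), Ddit3 (−1.11) and Chac1 (−1.08) called lower. The primed epiblast list lay at the 2.73rd percentile, with Cdh2 higher at 1.70 and Lefty2 (−1.31), Otx2 (−1.16) and Zic2 (−1.02) lower. No DNA methylation gene was called, and Dnmt3l was at −0.55, Dnmt3a at −0.29, Dnmt1 at −0.20 and Dnmt3b at −0.06. The other lists with at least 3 measured members lay between the 4th and the 97.2nd percentile.

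The fourth comparison set the knockdown array labelled with PRDM14 against the scramble array labelled with PRDM14. Of 10322 genes, 65 were at least 2-fold higher and 49 at least 2-fold lower on the knockdown array. The higher genes included Plac8 (2.32), the potassium channel Kcnk1 (2.27), the RNA-binding protein Mex3b (2.06), Slc39a8 (1.96), Dppa3 (1.95), Sycp3 (1.86), Cldn7 (1.62) and F3 (1.59). The lower genes included Ifitm3 (−1.99), Calcoco2 (−1.96), Trh (−1.95), Spink1 (−1.76), Manba (−1.55), Slc11a1 (−1.54), Aard (−1.52) and the eye and forebrain factor Pax6 (−1.43). With raised values Mex3b (0.56), Slc39a8 (0.77) and F3 (0.21) were under 2-fold, and 51 higher and 46 lower genes were counted. The pooled SD between probe sets was 0.16, and in 11 of 31 called genes with several probe sets all were past 2-fold.

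The naive pluripotency list lay below all random lists in the fourth comparison. Of 16 members 15 were below 0, the Krüppel-like factor Klf4 (−1.21) and the T-box factor Tbx3 (−1.04) were called, Tcl1 was at −0.83 and Nanog at −0.64, and the median was −0.45. Of 22 methylated germline genes 13 were above and 9 below 0, with a median of 0.12 (99.7th percentile), and 4 were called higher, Sycp3, Meioc (1.32), Ddx4 (1.25) and Dmrt1 (1.00). Without the filter the median over all members was −0.0115, with raised values it was 0.04 and within the random range with Meioc at 0.89, and Dmrt1 was at 0.99 after quantile normalization. Primed epiblast genes had a median of −0.15 (0.33rd percentile) and a mean of 0.03, with Pou3f1 higher at 1.23 and Lefty2 lower at −1.18, and the median was 0.0052 without the filter. Pou3f1 was at 0.73 with the mean of its probe sets and 0.24 on the other. General pluripotency (2.27th percentile), primitive endoderm (0.54th), neuroectoderm (1.22nd), fibroblast and feeder (2.43rd), Polycomb (1.83rd) and stress and hypoxia (0.62nd) lists also lay low, with medians from −0.18 to −0.09. The fibroblast and feeder list was at −0.066 without the filter, and with the mean of probe sets it was at −0.18 and the Polycomb list at −0.088, all within the random range. The other lists with at least 3 members lay between the 5.52nd and the 88.9th percentile. The Rhox list had 2 members above the filter here, Rhox5 at −1.36 and Rhox13 at −0.66.

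**Figure D3:**
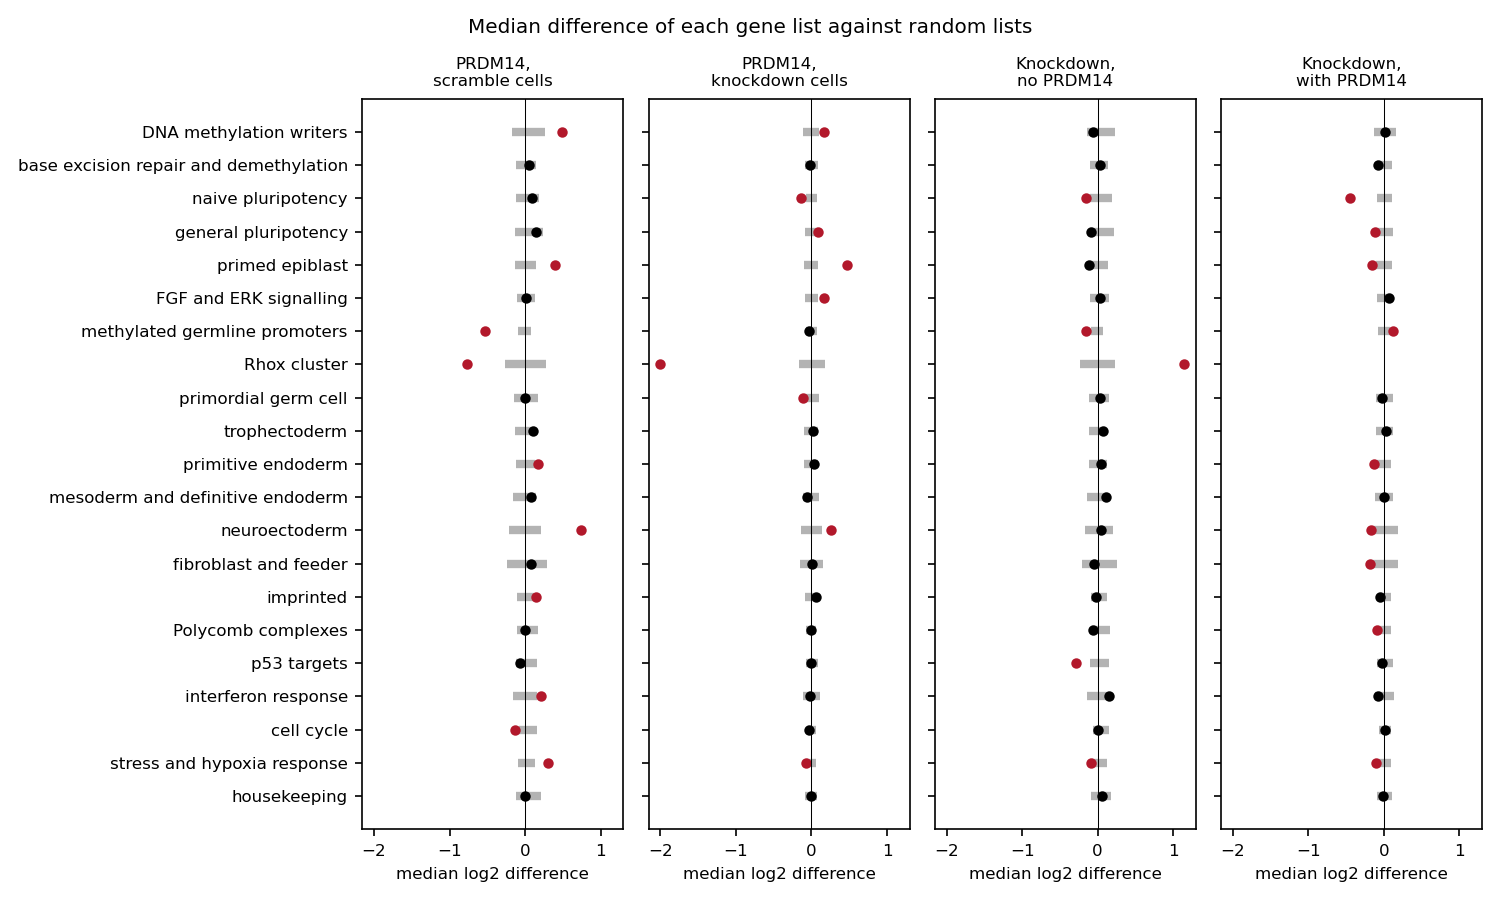
Median log2 difference of each gene list in the 4 comparisons (points) with the central 95% of 10000 random lists of the same size and expression (grey bars), red where the median lies outside the bar. The methylated germline list lies at −0.53 in the PRDM14 comparison in scramble cells and at −0.03 in knockdown cells, and the primed epiblast list at 0.40 and 0.47.

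The dependence of the PRDM14 difference on the knockdown was taken as the difference in knockdown cells minus that in scramble cells. It uses all 4 arrays, the scramble array among them. It was at least 2-fold positive for 103 and negative for 136 of 10519 genes. Sycp3 had the largest value, 3.86, followed by Cebpb (2.35, but −0.03 on a second probe set), Nupr1 (2.28), Gm20767 (2.25), the meiotic regulator Meioc (2.19), Kcnk1 (2.17), Phkb (2.12) and Plac8 (2.10). The most negative were Vim (−3.45), Calcoco2 (−3.19), Ifitm3 (−3.13), Htra1 (−3.05), Id1 (−2.69), Upp1 (−2.57), P3h4 (−2.52), Rhox5 (−2.51) and Sgms2 (−2.51). In 21 of 76 such genes with several probe sets all were past 2-fold. Of the 25 methylated germline genes 6 were 2-fold positive (5 with raised values, without Stag3) and none negative, and the median of 0.39 lay above all random lists. The p53 target (0.26, 99.9th percentile) and primed epiblast (0.27, 99.9th percentile) lists also lay high, and the Rhox (−0.81, 0.01st percentile), neuroectoderm (−0.47, 0.08th percentile), stress and hypoxia (−0.17, 0.99th percentile), base excision repair (−0.18, 1.29th percentile) and interferon (−0.23, 1.29th percentile) lists low. Phkb was at 0.96 with raised values, and 82 positive and 132 negative genes were counted. The interferon median was −0.098 without the filter, −0.12 with raised values and −0.17 with the mean of probe sets, and the stress and hypoxia median −0.028 without the filter, all within the random range, as were the lists not named here. Within this design the value has no error of its own and was not tested.

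The PRDM14 comparisons in the 2 backgrounds share no array, so their agreement could be measured directly. Across 10158 genes compared in both, Pearson's r was 0.233 and Spearman's rho 0.172, where genes are not independent replicates. Of these genes, 10 were called higher in both backgrounds (Cbr3, Dnmt3b, Efnb2, Hmgxb4, Mapkapk3, Pou3f1, Rian, Sox11, Trh and Trim2) and 7 lower in both (Afap1, Dppa3, Kit, Rhox6, Rhox9, Tfap2c and Urgcp), where independent lists of those sizes would share 0.365 and 0.253 genes. With raised values 12 of the 17 were called in both, all but Afap1, Pou3f1, Rhox6, Rhox9 and Urgcp. The lowest probe sets of Sox11 gave 0.24 in scramble and 0.18 in knockdown cells, and those of Rian 0.26 and 0.08. Looked up in the other background, the 109 genes called higher in scramble cells had a median of 0.25 in knockdown cells against 1.32 where they were called, and the 95 called lower had −0.26 against −1.22. In the reverse direction the 34 genes called higher in knockdown cells had a median of 0.63 in scramble cells against 1.21, and the 27 called lower had 0.05 against −1.22. Selection of extreme values shrinks any such look-up. For the knockdown comparisons, which also share no array, r was 0.0957 and rho 0.0963 across 10154 genes, with 4 genes higher in both (Galnt7, Klhl13, Mex3b and Rnf128) and 8 lower in both (Cpeb4, Egr1, Lefty2, Manba, Pfkp, Rpl39l, Slc25a16 and Trh), where independent lists would share 0.343 and 0.168. Of the genes compared in both, the 59 called higher without PRDM14 had a median of −0.03 with it, against 1.17 where they were called, and 8 of them were called lower there. The 38 called lower had −0.23 against −1.22, and 1 was called higher. In the reverse direction the medians were 0.21 against 1.19 for 59 higher genes and 0.04 against −1.21 for 45 lower genes.

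The average effects over the 4 arrays were tested with limma in an additive model, whose error is the difference between backgrounds. No gene passed a Benjamini-Hochberg adjusted p of 0.05 for PRDM14 or for the knockdown, and the smallest adjusted p was 0.782 and 0.802. At an unadjusted p under 0.05 there were 638 and 604 of 10519 genes, where 526 would be expected by chance. Limma's adjusted p depends on how many genes share the adjustment. The plan named no separate adjustment over single lists, and the smallest lists had 2 genes tested. Adjusted over the list alone, 21 genes from 8 of the 23 fixed lists passed 0.05 for PRDM14 and 6 genes from 4 lists for the knockdown, with no further adjustment for the number of lists. For PRDM14 these were Tet2, Dnmt3b and Dnmt3l, 5 primed epiblast genes (Pou3f1, Otx2, Lefty2, Sall2 and Fst), Spry2 and Phlda1 of the FGF and ERK list, Timp1 of the fibroblast list and 4 imprinted genes (Cdkn1c, Meg3, Rian and Mirg), all higher on the arrays labelled with PRDM14, and Rhox6, Rhox9, Rhox13, Tfap2c, Dppa3 and Kit, all lower. With raised values 9 of these genes passed for PRDM14 (Tet2, Dnmt3b, Dnmt3l, Dppa3, Kit, Tfap2c, Cdkn1c, Meg3 and Rian) and the same 6 for the knockdown. Phlda1, for example, read below the filter on 3 arrays and differed by 0.14 in scramble cells with raised values. The smallest adjusted p within the primordial germ cell list was 0.00434 and within the DNA methylation list 0.0168. For the knockdown they were Tet2, Lefty2, Pax6 and Rian, lower, and Car4 and Phlda2, higher, where other probe sets of Rian gave up to 0.10 without PRDM14. No methylated germline gene passed for PRDM14 (smallest adjusted p 0.146 over its list), where a difference that depends on the background enters the error. Of the sum of squares of the 3 contrasts over these genes, 41% belonged to PRDM14, 32.4% to the knockdown and 26.6% to their interaction. Noise alone, or 1 array apart from the rest, would give the 3 contrasts equal shares. The shares were unequal, with that of PRDM14 the largest and that of the interaction the smallest. This departure was not tested, and the shares do not measure effects of the conditions.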

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

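The tests of RNA degradation, of the size of the intensity trend, of the scramble array alone, of exchanged labels and of the naive to primed axis were chosen after the results they bear on were seen. The differences between comparisons given here were not tested, since each condition had 1 array.

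For 2 genes the PRDM14 difference was at least 2-fold in opposite directions in the 2 backgrounds. Calcoco2, an autophagy receptor, was at 1.63 in scramble and −1.56 in knockdown cells, a difference of −3.19, and Anxa2, a membrane-binding annexin, at 1.31 and −1.17, a difference of −2.48. Set the other way, as the knockdown without and with PRDM14, 9 genes were at least 2-fold in opposite directions. Besides Calcoco2 and Anxa2, with the same 2 values, these were Sycp3 (3.86), Vim (−3.45), Ifitm3 (−3.13), Upp1 (−2.57), P3h4 (−2.52), Rhox5 (−2.51) and Coch (−2.22), which was at 0.45 without PRDM14 with values below the filter raised to it. Probe sets without a named gene, which no comparison used, also passed the 2-fold rule: 87 for PRDM14 in scramble cells, 21 for PRDM14 in knockdown cells, 51 for the knockdown without PRDM14, 42 for the knockdown with PRDM14 and 100 for the dependence on the knockdown.

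The first pattern is that the scramble array stands apart from the other 3, with 49 genes at least 2-fold from all of them. RNA degradation is argued against, since the 3′ minus 5′ difference of the Actb control exceeded the mean of the other arrays by 0.0811 and that of Gapdh by 0.0762. An intensity-dependent trend left in the deposited values is argued against as the whole cause. Cyclic loess moved these genes by at most 0.0331 and 46 of the 49 remained apart. The deposited values already had a common distribution, so a trend altered by the authors' normalization could not be assessed. A part for such a trend stays open. After cyclic loess the array had 1.59 times as many such genes as the next (95% interval 0.976 to 2.62, treating genes as independent). That interval also leaves open whether the scramble array exceeds the next array. Of 2 gene lists written after single genes had been seen, ATF4 targets, the amino acid response, met the prediction made for them, with medians of −0.62 for PRDM14 (23 of 26 below 0) and −0.49 for the knockdown (25 of 26) against the scramble array, both below all random lists, and 0.54 for the dependence (24 of 26 above 0), above all of them, but also −0.07 (1.17th percentile) for PRDM14 in knockdown cells, which do not use that array, so a nutrient stress in the scramble culture may account for part of the pattern and enter the dependence. BMP targets other than Id1 and Id2 did not, at the 92.3rd percentile for PRDM14 although at the 99.98th for the knockdown.

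The second pattern is that Dnmt3b and Dnmt3l were higher, and Dppa3 and Tfap2c lower, on the arrays labelled with PRDM14. PRDM14 is known in embryonic stem cells as a repressor of Dnmt3b and Dnmt3l, the opposite direction, and a response to PRDM14 as labelled stays open. These genes passed the additive fit when adjusted over their lists alone, but not over all genes. That fit tests a difference between the labels, with 1 residual degree of freedom per gene, and not its cause. The scramble array as sole cause is argued against for Dnmt3b, Dppa3 and Tfap2c, which are among 19 genes called in both backgrounds, comparisons that share no array, of which 89.5% (exact 95% interval 66.9 to 98.7, treating genes as independent) went the same way (85.7% of 14, 57.2 to 98.2, with values below the filter raised to it), but stays open for Dnmt3l, called in neither and at 0.72 in knockdown cells. An exchange of the PRDM14 labels in both backgrounds could give it and stays open, because Prdm14 read below the filter with differences of 0.30 and 0.26, and every PRDM14 difference and every dependence value would then have the opposite sign and the knockdown comparisons without and with PRDM14 would trade places. A shift from naive to primed pluripotency is consistent with the knockdown cells (naive list at the 0.11th percentile, primed above all random lists) but not with the scramble cells, where the naive list lay at the 83rd percentile.

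The third pattern is that the list of methylated germline genes lay low with PRDM14 in scramble but not in knockdown cells. It rests on the PRDM14 labels. An exchange of them in both backgrounds, left open above, would make the list high with PRDM14 in scramble cells. The scramble array that stands apart would then be the array with PRDM14. Probe set choice stays open, since 2 of the 25 members had more than 1 probe set above the filter and taking the mean of a gene's probe sets left the median at −0.53. The scramble array alone cannot be told apart from a PRDM14 difference that depends on TET: the list's medians for the knockdown and for PRDM14 against that array differed by 0.38, with a bootstrap interval over genes from 0.01 to 0.69. The knockdown comparison with PRDM14, which does not use that array, had the list at the 99.7th percentile, but its median changed sign without the filter and came within the random range at 0.0366 with raised values. That comparison shares the scramble array labelled with PRDM14 with the PRDM14 comparison in scramble cells. Low germline values on this shared array alone would give both results and cannot be told apart either. The dependence on TET named by the design may hold and was not testable with 1 array per condition.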

How the results depend on the processing

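All alternatives but the raised values, chosen after the data were seen, were planned before the data were examined, and pseudocounts did not apply to log2 values. At 1.5-fold the counts of higher and lower genes were 444 and 405 for PRDM14 in scramble cells, 151 and 139 for PRDM14 in knockdown cells, 303 and 224 for the knockdown without PRDM14, 247 and 201 for the knockdown with PRDM14, and 460 and 497 for the dependence. At 3-fold they were 34 and 18, 8 and 5, 11 and 10, 8 and 4, and 16 and 33 in that order. Under the filter, scaling and probe set alternatives all counts stayed within 1.5 times, and the additive fit passed 0 genes under each of its alternatives. No scaling moved the median of all genes by more than 0.1. The deposited values already had a common distribution, so these scalings could change little. The authors' own normalization could not be varied.

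Without the filter 2 list medians changed sign in the knockdown comparison with PRDM14, primed epiblast (0.0052) and methylated germline (−0.0115). Without it these also came within the random range: primed epiblast (0.003), neuroectoderm (0.023) and stress (0.038) for PRDM14 in scramble cells, general pluripotency (0.083) and neuroectoderm (0.014) for PRDM14 in knockdown cells, fibroblast (−0.066) for the knockdown with PRDM14, and interferon (−0.098) and stress (−0.028) for the dependence. With the mean of probe sets the same held for DNA methylation (0.095), general pluripotency (0.079) and primordial germ cell (−0.070) for PRDM14 in knockdown cells, fibroblast (−0.18) and Polycomb (−0.088) for the knockdown with PRDM14, and interferon (−0.17) for the dependence. With raised values it held for methylated germline (0.0366) for the knockdown with PRDM14 and interferon (−0.1196) for the dependence, all counts stayed within 1.5 times, and 23 named gene values lost and 3 gained the call. Dropping the filter adds genes of lower signal, but the cause was not tested. The planned settings run on the lists were no filter, the mean of probe sets, and quantile and cyclic loess normalization. Over these together another 17 list values moved outside the random range and 383 kept direction and side. Under quantile and cyclic loess normalization and the mean of probe sets no named gene with a 2-fold call changed direction, 18 values lost and 6 gained the call. Of the look-up shares between backgrounds 3 moved. Signal over background was not measured per probe set, so how far low signals compress a difference is unknown. The lists of ATF4 and BMP targets were not run under the alternatives.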

Other observations

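Among imprinted genes, 2 noncoding RNAs of 1 imprinted locus were higher on the arrays labelled with PRDM14 in both backgrounds. Rian differed by 1.41 in scramble and 1.51 in knockdown cells and Meg3 by 0.86 and 0.98 on their brightest probe sets. The 3 Rian probe sets ranged from 0.26 to 1.41 in scramble and from 0.08 to 1.51 in knockdown cells, and the 6 Meg3 probe sets from 0.04 to 1.46 and from −0.0026 to 2.28. Phlda2, another imprinted gene, was higher on the knockdown arrays, by 0.74 without and 1.09 with PRDM14. Lefty2, a NODAL antagonist, was lower on the knockdown arrays in both states, at −1.31 and −1.18. Kit, the stem cell factor receptor, differed by −1.08 and −1.05 in the PRDM14 comparisons. These genes were chosen after their values were seen.

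The test of neighbouring genes was chosen after the Rhox genes had been seen. Adjacent genes called in the same direction numbered 8, 3, 3 and 2 in the 4 comparisons, more than in 99.8%, 99.9%, 98% and 86.9% of 10000 shuffles of gene order. The pairs include the Rhox genes that prompted the test and relatives such as Abcb1a and Abcb1b, whose probes may share targets. Without pairs whose symbols share their first 3 letters, 4, 1, 1 and 1 remained, more than in at most 81.7% of shuffles. The shuffles kept all pairs, which leans this comparison toward no excess. Whether pairs beyond gene families exceed chance placement was therefore not decided.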
